A study of Homo sapiens with 3 samples.

How the data were processed

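Mononuclear cells were isolated from blood on Ficoll and sequenced as 10x Genomics 3′ libraries, per the labels' protocols. The 3 libraries come from 1 donor with AML at day 0, day 2 and day 4, and GEO's labels gave each library its day. Per the submitters' processing notes, Cell Ranger 2.0.1, Seurat 2.2.1 and the genome build GRCh38 were used, without a statement of which step each served or in what order. Filters on cells, the annotation release and the treatment of doublets are not given in the sources used here.

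The authors deposited a matrix of raw UMI counts per gene and barcode, with 33694 genes and 4053 barcodes, and a table of 3968 cells that gives each cell's library, class, cluster, UMI count and gene count. The UMI sums of the matrix equal the deposited UMI counts in all 3968 cells. The other deposited columns, which hold library, class and cluster names, are text set by the authors and were used as they stand. The 85 barcodes outside the cell table have no library or class and entered no comparison. Each of them has under 251 genes or over 15% of UMIs from mitochondrially encoded genes, while the cells in the table have at least 251 genes and at most 14.7%. A second cell table that repeats the same cells and values in fewer columns was not used here.

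Cell classes are those of the authors' deposited annotation (12 classes). The main class is the blast class, and the comparison class is the sum of the 3 T cell classes. UMIs were summed over the cells of a class within each library and divided by the class total to give CPM. Sums have exact Poisson intervals, shares exact Clopper-Pearson intervals and ratios exact conditional binomial intervals, all at 95% and covering counting error only. A count of 0 was taken to allow up to 3 counts. Cells are not replicates, so no test was made between days. Fold values are ratios of CPM, and log2 values are log2((CPM + 10)/(CPM + 10)), which understates differences of low genes.

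The rules for classes, lists, markers and named genes were made before the data were examined. Named genes had 50 CPM or more on 1 of the 2 days and a ratio interval that excludes a 1.5-fold difference, and the 12 with the largest and the 12 with the smallest log2 values were taken, where as many passed. XIST and Y-linked genes, immunoglobulin and T cell receptor segments, HLA genes and genes that may be free RNA (over 10 times higher in another class of 50 or more cells on both days) were left out. Up to 4 members of each list with 20 CPM or more were named too, and BCL2, MCL1, BCL2L1, BCL2A1, DNMT1, CD34, MPO and CD36 in any case. The 41 lists hold 792 entries, all found in the matrix. A list's median covers members with 20 or more UMIs over the 2 days and needs 3 of them (1 for the RNA quality list). Its interval comes from 1000 resamples of the counts, and its percentile from 10000 random lists of the same size drawn from 50 bins of mean expression. Coordinates come from GENCODE 29 on GRCh38, where 22374 of the gene symbols matched.

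The count steps were tested on simulated counts drawn from the summed blast profile of day 0 and day 2 at the real depths. For day 2 against day 0 the ratio interval excluded 1 for 100% of 100 genes changed 2-fold, and covered the true value in 95.1% of 1790 genes. It also excluded 1 for 11.8% of the genes left alone, since the altered genes shift the total that CPM divides by. For day 4 against day 0, with 5 blasts, it excluded 1 for 51% of genes changed 2-fold up and 24% of those set to a ratio of 0.5. The simulated counts had counting error only, so coverage near 95% was set by the design and checks the computation. It does not speak of differences between cells, as among the day 4 blasts, where the 3 deepest held 97.0% of UMIs.

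For the alternatives, cells were clustered again (scanpy 1.11.5, values scaled to 10000, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolutions 0.5, 1 and 2 with igraph 0.11.9) and clusters named from the fixed markers. A cluster with under 3 markers above a log2 of 1 stayed unnamed. Blasts were also clustered alone at resolution 1, without the genes named as higher and the NF-kB and immediate early lists, into 9 sub-clusters. To bring the libraries to a like depth, UMIs per cell were scaled so that the T cells' median equals that of day 0. Blasts and other cells in the same window of scaled UMIs can still differ in depth. Scrublet called 29, 3 and 16 doublets on the 3 days. At day 2 this was 0.369% of cells, below the 0.5% set as a minimum, so the 5% of cells with the most UMIs were left out there, which removes 33 blasts. Further alternatives were size factors from the median of ratios, totals without ribosomal and mitochondrial genes, the mean over cells of each cell's share, cells thinned to 1000 UMIs, cells with 1000 or more UMIs, cells with under 10% mitochondrial UMIs, pseudocounts of 1 and 50 CPM, and list filters of 100 UMIs or none. Blasts with 2000 or more UMIs were an alternative chosen after seeing the data, as was the 1000 UMI limit for genes and lists. Shares over all barcodes in place of annotated cells were not run, since the 85 other barcodes have no class. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9 were used.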

Results

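Single-cell 3′ RNA libraries (10x Genomics) were made from peripheral blood mononuclear cells of 1 patient with acute myeloid leukaemia (AML), a cancer in which immature myeloid cells called blasts fill marrow and blood. The blood was sampled at baseline (day 0) and at day 2 and day 4 of treatment with azacitidine, a DNA methyltransferase inhibitor, and venetoclax, an inhibitor of the anti-apoptotic protein BCL2. Each day is 1 library. Day 0 holds 2365 annotated cells with 9455052 UMIs (unique molecular identifiers, each standing for 1 captured transcript). Day 2 holds 813 cells with 3703442 UMIs, and day 4 holds 790 cells with 2479056 UMIs. Median depth over all annotated cells was 2737, 3138 and 3021 UMIs per cell. With 1 library per day there is no replicate check and no test between days. The intervals given are 95% intervals that cover counting error only, and "higher" and "lower" describe these libraries.

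The first comparison asked which classes of blood cells differed in share between the days. The blast class (named "Blasts and Immature Eryth" by the authors) made up 27.7% of cells at day 0 (Clopper-Pearson interval 25.9 to 29.5, 654 cells). It made up 18.0% at day 2 (15.4 to 20.8, 146 cells) and 0.633% at day 4 (0.206 to 1.47, 5 cells). The share at day 0 was 1.54 times that at day 2 (exact conditional interval 1.29 to 1.86) and 43.7 times that at day 4 (18.6 to 135). Set against T cells, there were 51.9 blasts per 100 T cells at day 0 (47.2 to 57.1), 31.0 at day 2 (25.6 to 37.4) and 0.899 at day 4 (0.291 to 2.11). Of the 5 blasts at day 4, 2 had under 2000 UMIs, and without such cells the day 4 share was 0.381% (3 cells).

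Blast RNA outside the blasts was measured in the T cells, where UMIs of 12 progenitor and promyelocyte markers can come from free RNA in the droplets. Each marker held 50 CPM or more in day 0 blasts and at least 10 times its level in T cells. These include CD34 (a stem and progenitor surface protein), PRSS57 and MPO (enzymes of early granules). Their summed level in T cells was 94.0 CPM (counts of a gene scaled to a class total of 1e6, Poisson interval 83.9 to 105) at day 0 and 129.7 CPM (112 to 149) at day 2. Most of this difference lay in SOX4 (8.36 and 24.7 CPM) and MPO (16.4 and 33.1 CPM). In the blasts SOX4 was lower at day 2 (361 and 286 CPM). At day 4 the sum was 4.93 CPM (2.25 to 9.36), which is 5.24% of the day 0 level (2.38 to 10.1), and CLEC11A held 5 of its 9 UMIs. This measure was added after the shares had been seen.

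**Figure D1:**
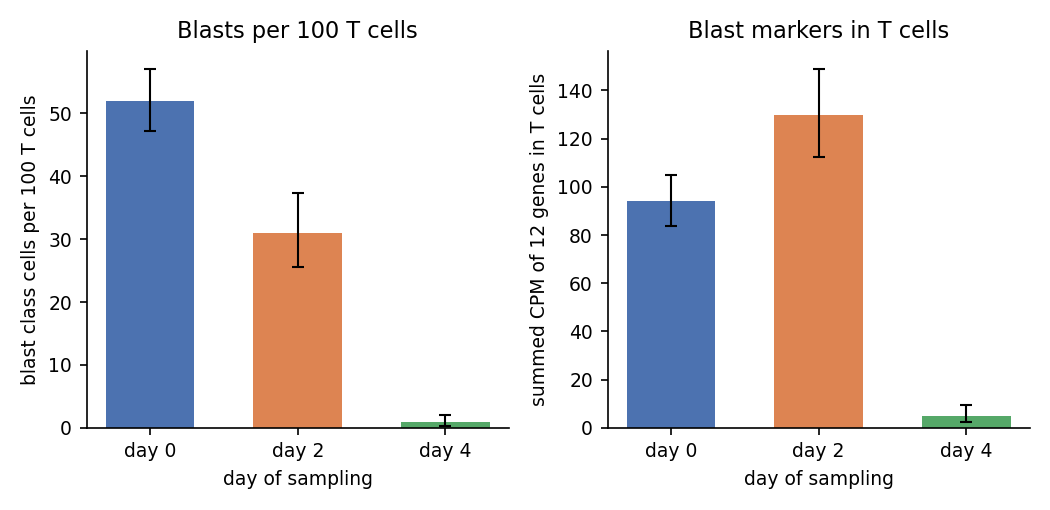
Left, blast class cells per 100 T cells on each day, with exact conditional 95% intervals, and right, the summed CPM of 12 blast markers counted in the T cells, with 95% Poisson intervals (1 library per day, bars are the measured values). Blasts per 100 T cells were 51.9, 31.0 and 0.899, while the markers in T cells were at 94.0, 129.7 and 4.93 CPM.

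Shares of the other classes are given of all cells and of the cells that were not blasts. The 3 T cell classes together held 53.3% of cells at day 0 and 70.4% at day 4, and 73.6% (71.5 to 75.7), 70.6% (67.0 to 74.0) and 70.8% (67.5 to 74.0) of the cells that were not blasts on the 3 days. The class named "Monocytes" held 12.4% (10.9 to 14.05) of the non-blast cells at day 0, 15.7% (13.1 to 18.7) at day 2 and 17.8% (15.2 to 20.7) at day 4. "Early Erythroids" numbered 29, 8 and 0 cells. For the 790 cells of day 4, a count of 0 allows a share of up to 0.380% by the rule of 3 counts, and up to 0.466% by the Clopper-Pearson interval. IgD B cells held 7.13%, 9.0% and 7.39% of non-blast cells, with overlapping intervals. "Mature Erythroids" (12, 2 and 1 cells), "Megakaryocytes" (36, 5 and 10), "Macrophages" (13, 5 and 3) and IgA B cells (17, 8 and 10) were few on every day.

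**Figure D2:**
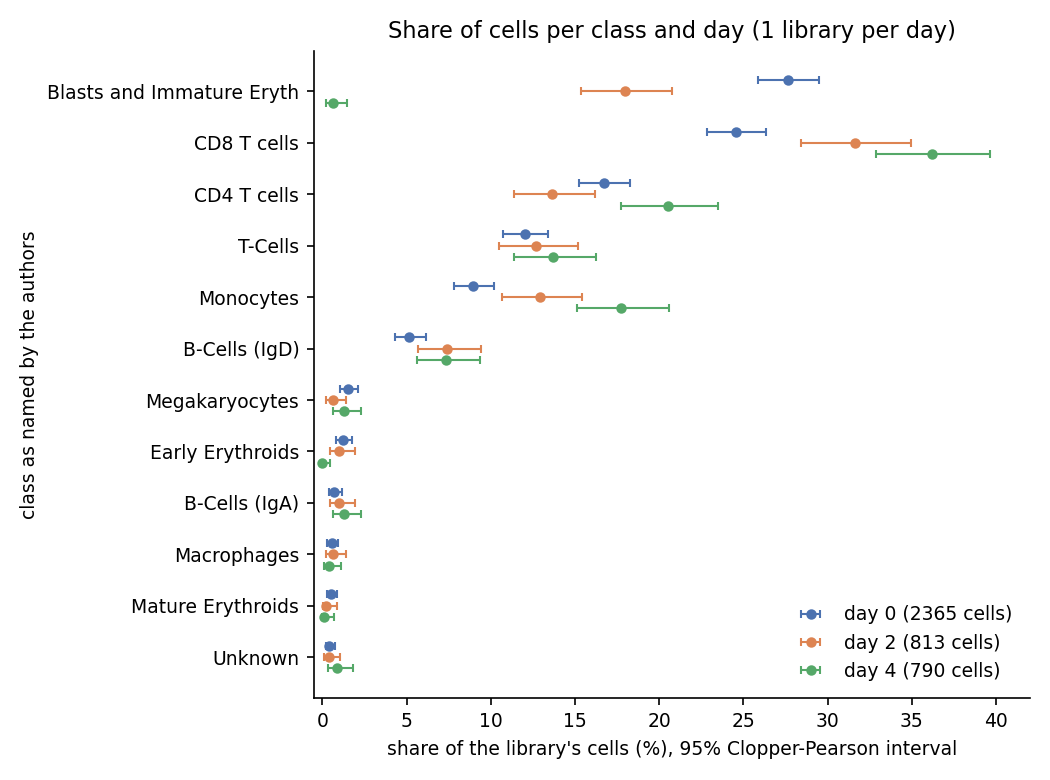
Share of each library's cells (x axis, percent, with 95% Clopper-Pearson intervals) in the 12 classes as named by the authors (y axis), coloured by day, 1 library per day. The blast class lies at 27.7%, 18.0% and 0.633%, and the class named Monocytes at 8.96%, 12.9% and 17.7%.

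Marker genes showed what each class held, over the 3 days together. The blast class held CD34 at 252 CPM, PRSS57 at 350.3 CPM and MPO at 357 CPM, and 0 UMIs of CD14, a monocyte receptor. The class named "Monocytes" held GNLY at 9648 CPM, NKG7 at 6266 CPM and KLRF1 at 737 CPM, which are genes of natural killer (NK) cells, while LYZ, lysozyme of monocytes, stood at 3.89 CPM. LYZ stood at 5385 CPM in the 21 cells named "Macrophages", which also held S100A8 at 14192 CPM and CD14 at 627 CPM. "Early Erythroids" held TPSB2 at 1663 CPM, MS4A2 at 694 CPM and HDC at 283 CPM, which are mast cell and basophil genes, beside the erythroid factors GATA1 at 70.6 CPM and KLF1. GNLY and NKG7 were also high in "CD4 T cells", at 2215 and 2697 CPM. The authors' names are kept here in quotation marks.

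The next comparison asked which genes the blasts of day 2 held at other levels than those of day 0, over 1551305 and 4722244 UMIs. Blasts were deeper at day 2, with a median of 10558 UMIs per cell against 6996.5 at day 0. Of the genes named by size, the 4 with the largest log2 differences were inflammatory. CXCL8, CXCL3 and CXCL2, which code for neutrophil-attracting chemokines, were 6.25-fold (5.76 to 6.78), 5.82-fold (5.08 to 6.67) and 6.09-fold (5.06 to 7.35) higher. CXCL8 stood at 186 and 1162 CPM. NFKBIA, the inhibitor that NF-kB itself induces, was 3.14-fold higher (2.80 to 3.51), at 398 CPM. The stress-induced transcription factor ATF3 was 3.42-fold higher (2.58 to 4.56), and ID2, a repressor of basic helix-loop-helix factors, 3.35-fold higher (2.59 to 4.34). The rule of size also named LAMP1 (3.61-fold), ATP2C1 (3.17-fold), H1FX (2.73-fold), CMPK1 (2.87-fold), RAC1 (2.51-fold) and PTMS (2.68-fold). CXCL2 and CXCL3 are close paralogs, so how reads were shared between them is uncertain. In GENCODE 29 annotation of GRCh38, CXCL8 lies on chromosome 4 from 73740506 to 73743716, CXCL3 from 74036589 to 74038807 and CXCL2 from 74097035 to 74099293 of the same chromosome. NFKBIA lies on chromosome 14 from 35401511 to 35404749. With an own clustering at resolution 2, CXCL8 was higher by 0.96 on the log2 scale in place of 2.58, as that clustering leaves a cluster with 225 blasts, led by CXCL8, CXCL3 and CXCL2, without a class. That cluster held 128 blasts of day 0 and 95 of day 2.

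The T cells of the same libraries held part of these differences. NFKBIA, LAMP1, CMPK1, RAC1 and PTMS were also higher in T cells at day 2, by log2 1.48, 1.26, 1.36, 1.49 and 1.01. For PTMS this rests on "CD8 T cells" (42 and 66 UMIs), as "CD4 T cells" held 16 and 2 UMIs and "T-Cells" 2 and 3. H1FX was higher in T cells by log2 0.47, against 1.33 in blasts. ID2 was well expressed in T cells, at 353 and 373 CPM, with a log2 difference of 0.08. CXCL8, CXCL3 and CXCL2 stood in T cells at 1.61%, 1.73% and 2.44% of the blasts' level at day 0, and at 2.18%, 1.78% and 2.91% at day 2, low shares such as free RNA gives. ATF3 and ATP2C1 held under 20 CPM in T cells on both days.

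**Figure D3:**
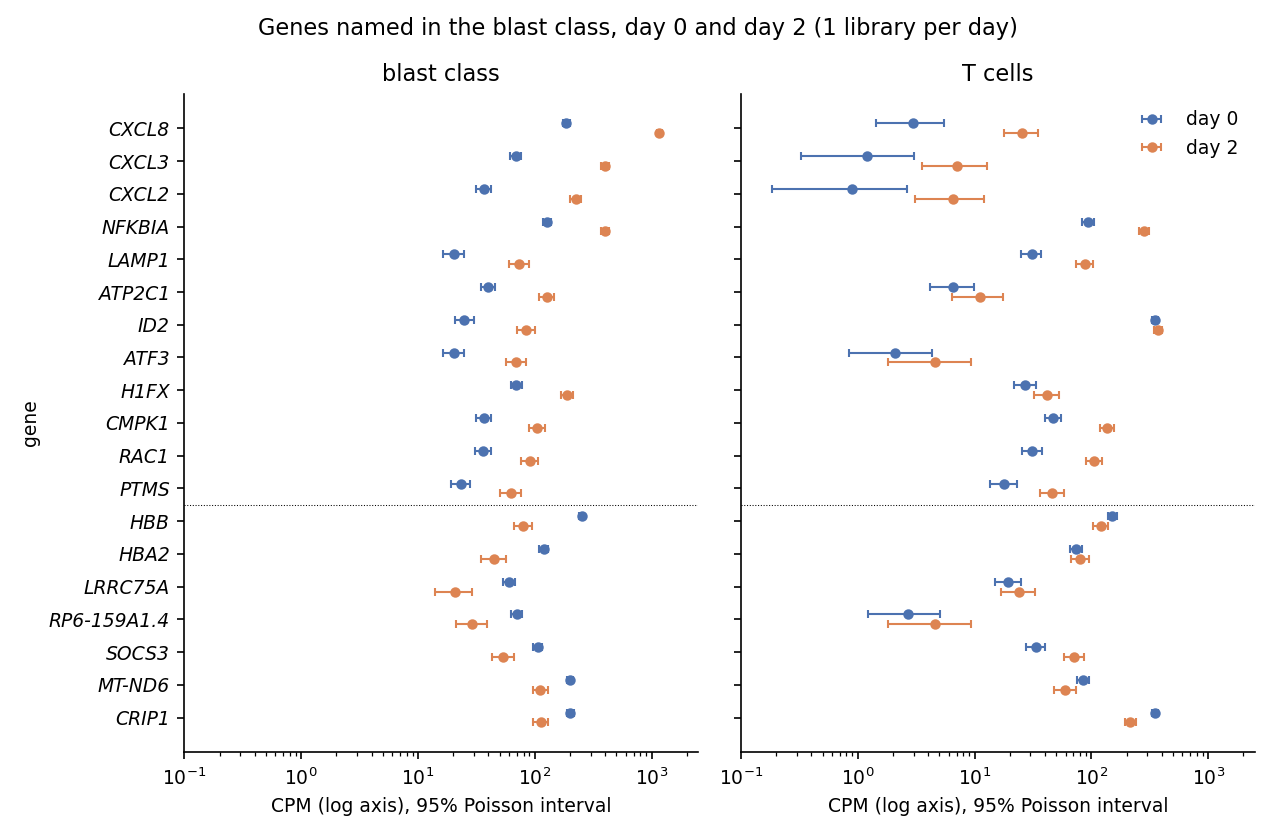
CPM (x axis, log scale, 95% Poisson intervals) of the 12 genes named as higher and, under the dotted line, the 7 named as lower in the blast class at day 2, for the blasts (left) and the T cells (right), 1 library per day. CXCL8 lies at 186 and 1162 CPM in blasts, while RAC1 is higher at day 2 in both classes and SOCS3 is lower in blasts and higher in the T cells together.

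The rule of size named 7 genes as lower. HBB, which codes for beta-globin, was at 251 CPM in day 0 blasts and 79.3 CPM at day 2, a 3.17-fold lower level (2.63 to 3.85), and HBA2 was 2.68-fold lower (2.08 to 3.49). HBA1 and HBA2 are near-identical copies that share reads, and globin RNA can be free RNA of red cells. HBB was also lower in T cells, by log2 -0.30, while HBA2 in T cells differed by log2 0.10. HBD, a globin gene used by immature erythroid cells, was higher, at 89.2 and 130.2 CPM, though with the opposite sign at resolution 2 (log2 -0.19). SOCS3, a feedback inhibitor of cytokine signalling, was 1.97-fold lower (1.56 to 2.52) in blasts and 2.13-fold higher (1.63 to 2.80) in the T cells together. By class, SOCS3 had ratios of 3.03 (1.36 to 6.78) in "CD4 T cells" and 2.46 (1.78 to 3.43) in "T-Cells", but 0.87 (0.40 to 1.79) in "CD8 T cells". LRRC75A was 2.94-fold lower (2.03 to 4.37) and RP6-159A1.4 2.42-fold lower (1.77 to 3.39). CRIP1 was 1.78-fold lower (1.52 to 2.11) in blasts, and its log2 difference in T cells was -0.67. MT-ND6, the mitochondrially encoded complex I subunit, was 1.80-fold lower (1.53 to 2.12) in blasts and differed by log2 -0.44 in T cells.

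Energy metabolism, the subject of the study's title, was read from gene lists. For each list the median log2 difference of its members with 20 or more UMIs is given. For part of the lists its percentile among 10000 random lists matched on expression is given too. The percentile describes these libraries and is no test. All values are of the whole blast class, whose sub-clusters had other shares at day 2. Of 9 sub-clusters, 2 held 9.17% and 12.7% of blasts at day 0 and 21.9% and 29.5% at day 2, and 3 held 8.87%, 16.1% and 10.4% at day 0 and 0.685%, 4.11% and 1.37% at day 2. The 13 mitochondrially encoded genes of the respiratory chain were lower in day 2 blasts, with 12 lower, a median of -0.16 (-0.18 to -0.10) and a percentile of 0.265. The T cells gave nearly the same value, -0.15 (-0.17 to -0.11), with all 13 lower. MT-CO1, a subunit of cytochrome c oxidase, stood at 5271 and 4488 CPM in blasts and 9403 and 8020.2 CPM in T cells. Of the nuclear genes of Complex V, the ATP synthase, 14 of 18 were lower in blasts, with a median of -0.10 (-0.15 to -0.03, percentile 1.945), against 0.01 (-0.05 to 0.07) in T cells. ATP5G2 stood at 1254 CPM in day 0 blasts and 1038 CPM in day 2 blasts. The blast median of Complex V was 0.01 with the own clustering at resolution 2, and that of the mitochondrially encoded genes was then -0.02. That clustering leaves 95 of 146 blasts of day 2 and 128 of 654 of day 0 in a cluster without a class, so these values are of a selected part.

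The other nuclear respiratory lists had medians in the blasts with intervals that include 0. Complex I had 19 of 38 members higher and a median of 0.00 (-0.06 to 0.07). The medians were 0.03 (-0.13 to 0.20) for the 6 genes of Complex II, 0.04 (-0.07 to 0.17) for the 9 of Complex III and -0.03 (-0.10 to 0.03) for the 11 of Complex IV. Pathways that use fuel had higher medians. The TCA cycle list had 15 of 20 members higher and a median of 0.18 (0.05 to 0.27, percentile 98.8). Glycolysis had 15 of 17 higher and a median of 0.13 (0.06 to 0.33, percentile 98.1). Its abundant enzymes ENO1 and PGK1 were 1.41-fold (1.34 to 1.49) and 1.45-fold (1.26 to 1.66) higher. Fatty acid oxidation had 14 of 18 higher and a median of 0.14 (0.03 to 0.22, percentile 93.6), but -0.02 when each cell was thinned to 1000 UMIs. In T cells the same 3 lists had medians of 0.12 (-0.06 to 0.17), 0.08 (0.02 to 0.21) and 0.08 (-0.04 to 0.18). The difference between the classes was not tested. Amino acid transport and glutamine use (0.10, -0.14 to 0.13) and glutathione and thiol redox genes (0.04, -0.05 to 0.11) lay near 0.

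**Figure D4:**
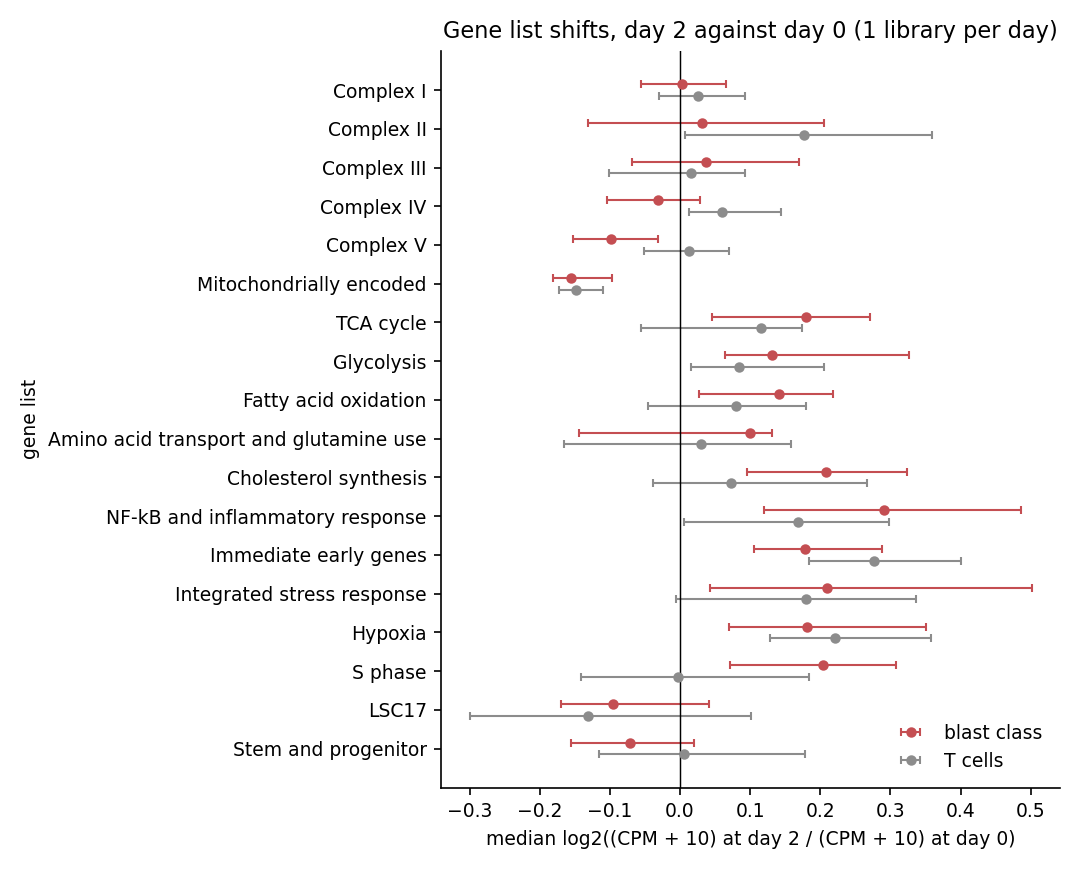
Median log2 ratio of day 2 over day 0 (x axis, 10 CPM added to each value, 95% intervals from resampled counts) for 18 gene lists (y axis), in the blast class (red) and the T cells (grey), 1 library per day. The mitochondrially encoded genes lie at -0.16 and -0.15 in the 2 classes, and the NF-kB list at 0.29 and 0.17.

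Several stress and signalling lists had higher medians in the day 2 blasts. The NF-kB and inflammatory list had 13 of 18 members higher, a median of 0.29 (0.12 to 0.49) and a percentile of 99.98, and its median was 0.11 with a pseudocount of 50 CPM. Immediate early genes had 13 of 18 higher and a median of 0.18 (0.10 to 0.29). Their median in T cells was 0.28 (0.18 to 0.40), with 14 of 16 higher. DUSP2, a phosphatase induced on activation, was 8.12-fold higher (6.46 to 10.3) in T cells, at 230.3 CPM. The integrated stress response had 8 of 11 higher and a median of 0.21 (0.04 to 0.50) in blasts, 0.18 (-0.01 to 0.34) in T cells and 0.02 in blasts thinned to 1000 UMIs. Its members DDIT4 and CEBPB were 2.22-fold (1.76 to 2.78) and 2.06-fold (1.42 to 2.96) higher in blasts, DDIT4 with the opposite sign at resolution 2 (log2 -0.33). Hypoxia genes had medians of 0.18 (0.07 to 0.35) in blasts and 0.22 (0.13 to 0.36) in T cells. Heat shock (0.04), interferon response (-0.07) and p53 target genes (-0.01) had intervals that include 0 in blasts.

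Cell cycle and identity lists went both ways. Of the S phase genes 18 of 19 were higher in day 2 blasts, with a median of 0.20 (0.07 to 0.31, percentile 99.8), though it was -0.09 after thinning. CDT1, which licenses replication origins, was 3.43-fold higher (2.27 to 5.2), and G2 and M phase genes had a median of 0.06 (-0.16 to 0.16). Cholesterol synthesis had 13 of 16 higher and a median of 0.21 (0.10 to 0.32). Early granule genes had 6 of 8 higher and a median of 0.25 (0.07 to 0.43), with MPO at 327 and 462 CPM. The 17-gene leukaemia stem cell score list (LSC17) had 10 of 16 lower and a median of -0.09 (-0.17 to 0.04), and the stem and progenitor list 15 of 26 lower with -0.07 (-0.16 to 0.02), both not told from 0. CD34 itself was 1.18-fold higher (1.05 to 1.31). MHC class II (-0.09, -0.17 to -0.02), ribosomal proteins (-0.07, -0.08 to -0.06, 41 of 50 lower) and platelet RNA (-0.28, -0.60 to -0.09) were lower, and T cells also had lower ribosomal protein genes (-0.05) and platelet RNA (-0.50). MHC class II turned to 0.17 at resolution 2. Red cell RNA went both ways, with HBB, HBA1 and HBA2 lower and 3 of 6 members, HBD among them, higher, so its median of -0.58 (-0.74 to -0.40) stands for no member.

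The drugs' targets and their relatives were read one by one. BCL2 stood at 25.6 and 30.9 CPM in day 0 and day 2 blasts, a ratio of 1.21 (0.85 to 1.70). MCL1, the anti-apoptotic relative that venetoclax does not bind, was 1.21-fold higher (1.03 to 1.41), and BCL2L1 had a ratio of 1.12 (0.61 to 1.95). BCL2A1 was 1.90-fold lower (1.14 to 3.33) on 18 UMIs. PMAIP1, which codes for NOXA, an antagonist of MCL1, was 2.21-fold higher (1.88 to 2.60) in blasts and 2.98-fold higher (2.05 to 4.37) in T cells. The BCL2 family list had a median of 0.05 (-0.13 to 0.12). DNMT1, a target of azacitidine, had a ratio of 1.34 (0.99 to 1.80), and DCK, the deoxycytidine kinase of nucleoside salvage, was 2.04-fold higher (1.59 to 2.62). Cancer-testis antigens, genes silenced by DNA methylation in blood, had 1 member with enough UMIs, too few for a value. CD36, a fatty acid transporter, had 2 UMIs in day 0 blasts and 0 in day 2 blasts.

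The blasts of day 4 were 5 cells with 52385 UMIs, of which the 3 deepest held 97.0%. A gene needs 3 UMIs, or 57.3 CPM, to stand above what a count of 0 allows. On this scale the median gene differed from day 0 by log2 -0.33, a shift at this depth that ranged from -0.13 with a pseudocount of 50 CPM to -1.25 after thinning, so lists are read against their matched random lists, and the T cells' median gene lay at 0.02. MPO had 0 UMIs, at least 5.70-fold below its day 0 level of 327 CPM, and FKBP5 and DYNLT1 had 0 as well, at least 2.23-fold and 1.96-fold lower. H1F0 had 2 UMIs, for a ratio of 0.15 (0.02 to 0.56). Genes named as higher rested on few UMIs, such as NPW with 17 (7.55-fold, 4.31 to 12.4) and DLK1 with 6 UMIs from 1 cell. Of the 18 genes named by size, 12 had 5 or fewer UMIs. MCL1 was 2.32-fold higher (1.26 to 3.92) on 14 UMIs, and BCL2, BCL2L1, BCL2A1 and DNMT1 had 1 UMI each. After thinning MCL1 stood at log2 -3.66, but thinning leaves 3 blasts of 1000 UMIs each, where the median gene lay at -1.25. The sign of MCL1 there decides nothing.

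Among lists at day 4, 20 of 26 stem and progenitor genes were lower, with a median of -0.72 (-1.08 to -0.50) against -0.05 for random lists. T cells, which hold such RNA as background, gave -0.75 (-0.86 to -0.52). S phase genes stood at 0.96 (0.36 to 1.31, random lists 0.18) and at -1.05 after thinning, where the median gene lay at -1.25. Of these, FEN1, HELLS, MCM2 and POLA1 held 2, 3, 2 and 2 UMIs, for each gene from 1 cell. The interval does not cover such differences between cells. The mitochondrially encoded genes stood at 0.29 (0.19 to 0.45, random lists 0.04), and Complex V at -0.28 (-0.55 to -0.05, random lists 0.07). NK and cytotoxic RNA was higher in these 5 cells, with a median of 1.17 (0.45 to 1.53), and T cell RNA stood at 0.60 (-0.65 to 1.06). The NK and cytotoxic list stood at -1.91 after thinning and at -0.21 at resolution 2 (1 blast). The median gene lay at -1.25 and -0.77 in these settings, so the signs decide nothing.

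T cells, with 1260, 471 and 556 cells, gave a comparison within the same blood. At day 4 against day 0 their mitochondrially encoded genes had a median of -0.06 (-0.10 to -0.02), ribosomal proteins -0.07 (-0.09 to -0.07), immediate early genes 0.07 (0.03 to 0.17) and NF-kB genes 0.14 (0.02 to 0.27). RAC1 stood at 31.0, 105 and 31.2 CPM in T cells on the 3 days, and LAMP1 and CMPK1 had ratios of 1.41 (1.04 to 1.91) and 1.41 (1.11 to 1.80) at day 4. Cytotoxic genes were higher in the T cells together on both days, with list medians of 0.18 (0.13 to 0.26) and 0.28 (0.22 to 0.32). The mix of T cells differed too, with "CD8 T cells" at 46.1%, 54.6% and 51.4% of them on the 3 days. Within "CD8 T cells" the medians were 0.16 (0.11 to 0.25) and 0.25 (0.18 to 0.30), within "CD4 T cells" 0.14 (0.048 to 0.25) and 0.20 (0.15 to 0.31), and within "T-Cells" 0.26 (0.0014 to 0.50) and 0.12 (-0.047 to 0.49). GZMH, which codes for granzyme H, stood at 852, 1204 and 1242 CPM. FKBP5, a gene induced by glucocorticoids, stood at 86.6, 39.6 and 40.5 CPM in T cells and at 127, 72.8 and 0 CPM in blasts.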

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

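The tests of the class named "Monocytes", of free blast RNA and of cells at scaled depth were chosen only after the results were seen. The other tests on the blast share and on the inflammatory genes were set earlier, before they were run, but for patterns already seen.

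The NF-kB list stood at -0.63 (-1.06 to -0.20) in day 4 blasts and 0.14 (0.02 to 0.27) in T cells, a difference of -0.78 between opposite directions that was not tested. Complex V stood at -0.28 in day 4 blasts and 0.05 in T cells, a difference of -0.33, also untested, and the mitochondrially encoded genes stood at 0.29 and -0.06, a difference of 0.35, untested. All 3 rest on 5 blasts, whose median gene lies at -0.33. The random lists matched to these 3 on expression lay at -0.06, 0.07 and 0.04 in the blasts. SOCS3 was lower in day 2 blasts (log2 -0.86) and higher in the day 2 T cells together (0.91, but -0.12 in "CD8 T cells"), an untested difference of -1.77.

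The 85 barcodes outside the cell table hold 104779 UMIs, 0.666% of all, and a signal that no comparison uses. Their median share of mitochondrially encoded UMIs is 22.2%, against 3.85% in annotated cells. HBB makes up 178452 CPM of their RNA (175903 to 181028), against 1218 CPM in annotated cells, and the platelet genes PPBP and PF4 stand at 1508 and 582 CPM against 34.9 and 18.4 CPM.

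The blast share was far lower at day 4. An upper limit on UMIs is argued against by the 0.685% of day 2 blasts within 10% of the highest count. Removal after capture, by filters or class names, is argued against as the whole cause by blast markers in T cells at 5.24% of day 0. These markers stood at 138% of day 0 at day 2, where the blast share was lower, so they do not exclude removal of a part. A loss of large cells at capture, as part of the fall, cannot be told apart from a loss of blasts. It would also take other cells (outside the blast and "Early Erythroids" classes) of over 5000 UMIs. These made up 2.62% at day 0 and 3.31% (2.17 to 4.82) at day 4, which by the reading set earlier goes against such a loss. T cells were deeper at day 4, however (median 3213.5 UMIs against 2521.5 at day 0), so 5000 UMIs was a lower bar there. With UMIs scaled to equal T cell medians the day 4 share was 0.892% (0.359 to 1.83). The deep "Early Erythroids" numbered 29 and 0 cells, which goes with such a loss. Against it as the whole cause go blasts per other cell among cells of over 5000 UMIs at equal depth. They stood at 121% of day 0 at day 2 and 4.19% (0.685 to 19.4) at day 4. Blasts there were deeper than the others, however (median 8627 against 6025 at day 0). Between 5000 and 7000 UMIs the depths were closer (median 6027 against 5565.5 at day 0). Blasts per other cell in that window stood at 82.8% of day 0 at day 2 and 0% (0 to 17.1) at day 4. The day 4 value rests on 0 blasts and 7 other cells. Between 2000 and 4000 UMIs blasts per other cell stood at 0% (0 to 7.34, or up to 5.83% by the rule of 3 counts) at day 4. They stood already at 11.1% at day 2, so this window decides nothing. Open are thus a loss of large cells at capture and removal after capture, each as part of the fall, and a loss of blasts before capture. A loss before capture could lie in the patient (the treatment, untested without another donor or an untreated series) or in the handling of that sample.

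The 12 genes named as higher in day 2 blasts, among them CXCL8, CXCL3, CXCL2, NFKBIA and ATF3 of inflammation and stress, had a median log2 of 1.44. The sub-clusters' shares of the class did differ between the days. This cannot be told from a change of expression or depth in the same blasts. A shift between blasts that other genes tell apart is argued against as the whole cause. In the 4 of 9 sub-clusters with 20 or more cells on both days, made without these genes, the lowest median was 1.32. CXCL8 was higher in each (56.4 and 302 CPM in the lowest). A subset told apart by these genes alone was not tested and stays open. At resolution 2 a cluster led by CXCL8, CXCL3 and CXCL2 held 128 of 654 blasts at day 0 and 95 of 146 at day 2. A rise in all blasts would also give this. Deeper cells are argued against by a median of 1.61 among blasts of 5000 to 12000 UMIs. Handling of the whole day 2 library stays open, as T cells gave a median of 1.31 for the 8 genes with 20 CPM or more there, against 1.38 in the blasts, and 1.26 against 1.33 without CXCL8. The CXCL8 UMIs in T cells stand at 2.18% of the blasts' level, as free RNA could, though unevenly over the T cell classes. Without CXCL8, NFKBIA is alone of the inflammatory genes. Handling may account for genes such as RAC1 and NFKBIA, whereas ID2 (0.08 in T cells) does not follow it, H1FX follows it in part (0.47) and the chemokines were not tested by it, so the treatment stays open as well, untested.

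The class named "Monocytes" carried NK cell genes. Monocytes that took up free NK RNA are argued against by LYZ at 3.89 CPM, where the "Macrophages" held 5385 CPM. NK cells under another name would put the class with NK clusters, and 97.4% of its 457 cells lay in own clusters led by NK markers, so the class is likely to hold NK cells. No biological explanation was tested.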

How the results depend on the processing

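Limits of 1000 UMIs per cell for genes and lists, and of 2000 UMIs per blast, were added after the data were seen. The limit of 1000 UMIs removed no cell of day 0 or day 2, so it left the values of those days unchanged. The blast share kept its order (day 0 above day 2 above day 4) in all 7 alternatives. At day 2 it was 14.6% without doublets, where leaving out the deepest cells removes 33 blasts. At resolution 2 of the own clustering it was 20.8%, 5.78% and 0.127% on the 3 days, where 225 blasts fall in 1 unnamed cluster. Shares over all barcodes were not run, as the 85 others have no class.

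Among list medians in day 2 blasts, 526 of 598 alternative values lay within the counting interval, 68 outside it and 4 turned the sign of a value whose interval excludes 0. The same counts were 1869, 134 and 12 of 2015 for named genes, and 534, 22 and 1 of 557 for lists in T cells at day 2 and 521, 34 and 2 at day 4. At day 2 the counts within the interval include every value of the limit of 1000 UMIs per cell, which was within by construction. Values with the other sign where the interval includes 0, as for Complex I, or within the interval, are counted as within or outside it. They numbered 62 for lists and 41 for genes in day 2 blasts, and 69 and 33 for lists in T cells at day 2 and day 4. The median of all genes in day 2 blasts lay between -0.07 and 0.01 in every alternative.

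In day 2 blasts, size factors by the median of ratios gave the mitochondrially encoded genes -0.20. Totals without ribosomal and mitochondrial genes gave them -0.22, Complex I -0.056 and Complex V -0.16, in part because this moves all genes down. Leaving out doublets gave Complex I -0.059. A pseudocount of 50 CPM gave the NF-kB list 0.11, as it shrinks all log2 values. Thinning to 1000 UMIs, which discards most UMIs of a blast, gave Complex V -0.21, mitochondrially encoded genes -0.21, the TCA cycle 0.28 and the integrated stress response 0.020. It turned the sign of fatty acid oxidation (-0.024), S phase (-0.086), CALR (-0.0022), DDIT3 (-0.69), IDH2 (-0.086), MCM5 (-0.17), TIMM8B (0.20) and UQCRC2 (-0.0062).

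Resolution 2, with 47 blasts at day 2, gave Complex I 0.092, Complex II 0.22 and mitochondrially encoded genes -0.025. It turned the sign of Complex V (0.011), MHC class II (0.17), ATP5I (0.053), DDIT4 (-0.33), HBD (-0.19), HSP90AB1 (0.035), MALAT1 (-0.021) and MAP1LC3B (-0.035). Resolution 2 leaves out the unnamed cluster led by CXCL8, CXCL3 and CXCL2, with 95 of 146 blasts of day 2 and 128 of 654 of day 0. Its values are thus of a selected part of the blasts, with fewer cells and UMIs. The cause of the changes was not tested.

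For day 4 blasts, 510 of 598 list values lay within the interval, 82 outside and 6 turned sign in that sense, and for genes 305, 12 and 8 of 325. Another 68 list values and 4 gene values had the other sign without being counted so. Thinning leaves 3 blasts and turned S phase (-1.05), NK and cytotoxic RNA (-1.91), ARHGAP12 (-0.69), AVL9 (-0.82), DLK1 (-0.21), MCL1 (-3.66), METTL15 (-1.15) and NUB1 (-1.50). Resolution 2 leaves 1 blast and turned MHC class II (0.19), NK and cytotoxic RNA (-0.21), ARHGAP12 (-0.62) and PHLDA1 (-0.33). The median gene lay at -1.25 after thinning and at -0.77 at resolution 2, so a turn to a negative value there decides nothing. A minimum of 100 UMIs, which keeps fewer members, turned p53 targets (0.15) and cholesterol synthesis (0.29). In T cells, size factors by the median of ratios turned Complex IV at day 2 (-0.00022), and Complex V (-0.0066) and glycolysis (-0.0054) at day 4, all values near 0. Depth limits day 4 most, as 5 blasts with 52385 UMIs leave a floor of 57.3 CPM.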

Other observations

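Some lists belong to no comparison above. In day 2 blasts, DNA methylation machinery had a median log2 of 0.07 (-0.12 to 0.25), histone genes -0.06 (-0.28 to 0.11), MYC targets -0.03 (-0.11 to 0.06), and lysosome and autophagy genes 0.03 (-0.02 to 0.17). Mitochondrial translation stood at -0.01 (-0.09 to 0.07), mitochondrial import and chaperones at -0.05 (-0.11 to 0.04) and monocyte differentiation at -0.07 (-0.30 to 0.01). RNA of other cells in the blast class gave 0.17 (-0.01 to 0.32) for NK and cytotoxic genes, -0.04 (-0.20 to 0.17) for T cell genes and -0.02 (-0.23 to 0.19) for B cell genes. The genes of the RNA quality list went opposite ways, with MALAT1 at log2 0.28 and NEAT1 at -0.28, so their median of 0.00 says nothing of RNA quality.

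The class named "Monocytes", which carried NK cell genes, also held DUSP2 5.10-fold higher at day 2 than at day 0 (2.40 to 11.8), RAC1 3.72-fold (2.19 to 6.51), CMPK1 5.01-fold (2.52 to 10.7) and LAMP1 3.64-fold (1.94 to 7.11). PRF1, which codes for perforin, stood at 1059, 1777 and 1447 CPM in this class on the 3 days. It is named here after its values were seen.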
